A study of Homo sapiens with 6 samples.

How the data were processed

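RNA was sequenced from U87 cells, an established human glioblastoma line, in 6 libraries. Per the labels, cells were transduced with lentivirus carrying a control short hairpin (shCtrl) or 1 of 2 hairpins against CCDC50 (shCCDC50-1 and shCCDC50-5, called hairpin 1 and hairpin 5 here) and were then selected with puromycin. Each of the 3 groups held 2 libraries. RNA was extracted with Trizol and made into libraries by standard Illumina methods. Whether RNA with a poly(A) tail was selected is not given in the sources used here.

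The deposited table holds raw counts per gene, which the authors made from reads trimmed with Trim Galore and aligned with HISAT2 to hg38, per the submitters' processing notes. Versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. All values are whole numbers, 1 column per library, with an Ensembl identifier and a symbol per gene. Of 67130 rows, 36493 had no counts. Gene types, exon lengths and positions came from GENCODE v29, which matched 58453 rows by identifier. Exon length here is that of the longest annotated transcript of a gene, whichever transcript was expressed. Rows for rRNA were found with the RefSeq annotation of GRCh38.p14. For that reason, and because another annotation release may have been used by the authors, lengths are approximate. Overlapping genes whose strand was not known may share reads.

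Totals per library ran from 38885857 to 67729439 counts. Intervals on shares of counts are 95% exact binomial (Clopper-Pearson) intervals, and a group with no counts was given a floor of 3 counts pooled over its libraries. Both cover counting error only, since reads carried no molecular identifiers as far as the sources say.

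Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, which left 18724 rows, TMM size factors, and the robust quasi-likelihood fit and F test with the 3 groups as levels and no covariate. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all rows tested. The comparisons were each hairpin against the control, hairpin 5 against hairpin 1, and the mean of the hairpins against the control. Standard errors are those of the fitted log2 fold changes, and CPM values use TMM-scaled library sizes. Of the tested rows, 13947 were protein-coding, and 30 symbols occurred more than once.

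Before the data were examined, 31 lists of genes were written from general knowledge: EGFR family and ligands, MAPK feedback and output, endosomal sorting and recycling, autophagy and lysosome, interferon response, NF-kB targets and cytokines, class I antigen presentation, G1/S and DNA replication, G2/M and mitosis, p53 targets, ER stress and ATF4, hypoxia and glycolysis, cholesterol biosynthesis, fatty acid synthesis, extracellular matrix, matrix proteases and inhibitors, TGF-beta targets, YAP/TAZ targets, glioblastoma mesenchymal state, glioma stem and proneural genes, markers of astrocytes, neurons, epithelium, immune cells, and endothelium with pericytes, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear OXPHOS genes, replication-dependent histones, NRF2 targets and apoptosis regulators. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry were also run. Adjustment over the members of a list alone is given where stated.

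Genes were named by a rule fixed at the same time. CCDC50 and EGFR were always named. Other named genes were protein-coding, had no placeholder symbol, and had a mean of at least 5 CPM in the highest group. They were the 8 higher and 8 lower genes called by both hairpins (none qualified), the 6 higher and 6 lower called genes with the largest change for each hairpin and for hairpin 5 against hairpin 1, and up to 4 members per list with the smallest adjusted p in the mean of the hairpins. A few list members and low counts of called genes outside this rule are also named where stated, chosen after their values were seen.

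The correlation of fold changes between the hairpins was set beside 40 simulated data sets in which unchanged knockdown groups shared 1 control group. All simulated libraries had the same spread per gene. Splitting the 2 control libraries would leave 1 library on each side, so no fit with separate controls was run. The test was also tried on simulated data with the fitted spread, in which edgeR recovered 57.6% of 4-fold changes for hairpin 1 and 54.1% for hairpin 5, but 4.76% and 15.5% of 2-fold changes. False calls numbered 18 and 14 among 18523 unchanged genes. Recovered changes of 2-, 4- and 8-fold numbered 3, 34 and 50 for hairpin 1 and 11, 40 and 43 for hairpin 5. In this single simulated data set, false calls were thus a larger share of all calls than the adjusted p threshold of 0.05. With the fitted dispersion of each gene divided by 4 in every group, 55.6% and 56.3% of 2-fold changes were recovered. That smaller spread was a setting and was not estimated from the control libraries.

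Alternatives fixed at the same time as the lists were RLE and upper-quartile size factors, no filter, a filter of 1 CPM in 2 libraries, only rows with a symbol, DESeq2 1.42.0, limma-voom, fits of the compared groups only, replicate number as a block, a fold-change minimum of 2, an adjusted p under 0.01, each library left out in turn, and the other set tests. Chosen after seeing the data were limma-voom with sample quality weights, removal of a trend with exon length within each library, leaving out 2 libraries together (shCCDC50-1 replicate 1 and shCCDC50-5 replicate 2), and camera with a mean-variance trend. Where a library was left out, its partner was taken to vary like the other groups. With the 2 libraries left out together, only the shCtrl pair gave the spread. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads, splicing, protein and EGFR at the cell surface were not analysed here, and the regrouping of samples was not run because groups of 2 are too small.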

Results

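Expression was measured in U87 glioblastoma cells with a control hairpin or 1 of 2 hairpins against CCDC50, which encodes a coiled-coil protein that binds ubiquitin and has been linked to EGFR signalling. The series asks how CCDC50 bears on glioblastoma growth through the return of EGFR to the cell surface. Depth was 67729439 and 67545091 counts in the shCtrl libraries, 38885857 and 62673180 with hairpin 1, and 50224165 and 60164705 with hairpin 5. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between samples, which may be technical.

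The libraries differed in composition. Rows taken as rRNA were identified mainly by position: 99.9% of their counts lay on rows that overlap 18S genes. These were chiefly rows typed as lincRNA on the minus strand, such as FP236383.5. Rows for rRNA held 13.2% of counts in hairpin 1 replicate 1 (exact binomial interval 13.2 to 13.2%), 2.62% (2.61 to 2.62%) and 2.72% (2.72 to 2.73%) in the hairpin 5 libraries, 0.0481% (0.0476 to 0.0487%) in hairpin 1 replicate 2, and 0.235% (0.233 to 0.236%) and 0.0267% (0.0263 to 0.0271%) in the controls. Small non-coding RNA held 0.495% in hairpin 1 replicate 1 and between 0.0038% and 0.0663% elsewhere. Mitochondrially encoded genes held 4.48 to 7.08% of counts. Across protein-coding genes, the level in hairpin 5 replicate 2 fell with exon length (Spearman rho −0.459 across genes, which are not independent replicates, for the log2 difference from the mean of the other libraries), while rho lay between 0.0838 and 0.264 in the other 5 libraries. Between the 2 libraries of a group, the SD of the log2 difference was 0.691 for shCtrl, 0.995 for hairpin 1 and 1.05 for hairpin 5. The hairpin 5 libraries lay apart from the rest on the first principal component (32.7% of variance), at 36.5 and 102 against −52.8 to −23.9. Sample quality weights, computed after the data were seen, were 0.313 and 0.284 for hairpin 5 against 1.51 to 2.18 in the other 4 libraries. With 2 libraries per group such weights measure how far the libraries of a pair differ from each other, not which of them deviates.

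**Figure D1:**
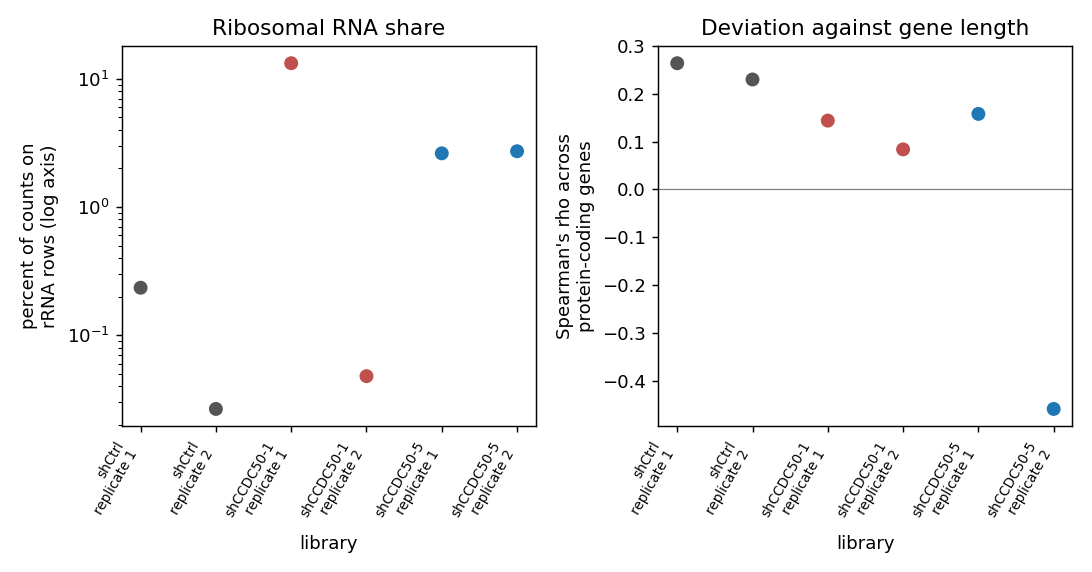
Share of counts on rRNA rows (percent, log axis) and Spearman rank correlation, across protein-coding genes, of exon length with the log2 difference from the mean of the other libraries, for each of the 6 libraries. Hairpin 1 replicate 1 holds 13.2% rRNA and hairpin 5 replicate 2 has a rho of −0.459.

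The first comparison asked how far each hairpin lowered its target. CCDC50 (ENSG00000152492, hg38 chromosome 3, 191329077 to 191398670, plus strand, with exons that overlap UTS2B) stood at 92.4 ± 2.93 CPM with shCtrl (SD, n = 2), 26.8 ± 3.50 with hairpin 1 and 59.6 ± 11.5 with hairpin 5. This is 28.9% of the control with hairpin 1 and 64.5% with hairpin 5, and the groups did not overlap. The log2 change was −1.79 with hairpin 1 (SE 0.206, 95% interval −2.28 to −1.30) and −0.63 with hairpin 5 (SE 0.200, −1.11 to −0.15). By edgeR's quasi-likelihood test over all genes the adjusted p was 0.0668 and 0.201, and neither passed. Without shCCDC50-5 replicate 1 they were 2.42e-05 and 0.000473, and without shCCDC50-5 replicate 2 they were 2.16e-05 and 0.0524. Hairpin 5 left more CCDC50 RNA than hairpin 1 by 1.16 (0.67 to 1.64, adjusted p = 0.0718).

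EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628, plus strand, overlapping EGFR-AS1), the receptor tyrosine kinase the series is about, did not pass in any comparison. Its level was 118 ± 14.8 CPM with shCtrl, 121 ± 0.389 with hairpin 1 and 92.6 ± 27.4 with hairpin 5 (SD, n = 2). The log2 change was 0.04 with hairpin 1 (95% interval −0.53 to 0.60, edgeR adjusted p = 0.976), which was −0.09 without shCtrl replicate 2, and −0.35 with hairpin 5 (−0.92 to 0.22, adjusted p = 0.494). With shCCDC50-5 replicate 1 left out, EGFR passed for hairpin 5 at −0.72 (adjusted p = 0.00123) and for the mean of the hairpins at −0.34 (0.0193), and these then rested on replicate 2, the library in which level fell with length. EGFR at the cell surface was not analysed here.

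**Figure D2:**
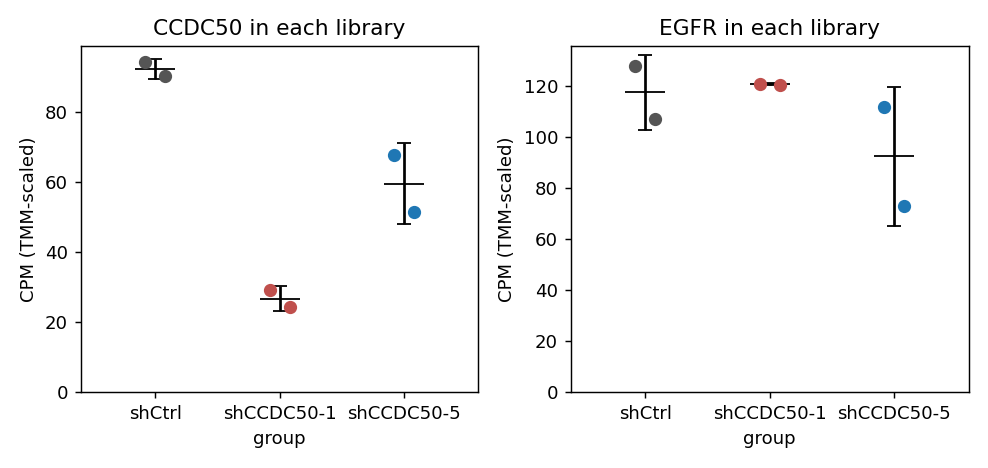
CCDC50 and EGFR in CPM for each library (points), with the group mean (horizontal line) and SD (error bar), on axes from 0. CCDC50 lies between 90.3 and 94.4 CPM in the controls and between 24.3 and 67.8 CPM in the 4 knockdown libraries.

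With hairpin 1, genes of the ER stress and ATF4 list lay lower: 31 of 33 members were negative and 2 positive, with a median log2 change of −0.58 and medians of −0.56 and −0.52 in the 2 libraries. The list holds targets of the integrated stress response such as CHAC1, which degrades glutathione (−2.22, SE 0.322), SLC7A11, the cystine importer (−2.06, SE 0.299), and ASNS, which makes asparagine (−1.60, SE 0.190). The list passed camera (adjusted p = 1.91e-08) and fry (0.00229), with adjusted p = 0.177 with an estimated correlation. No member was called over all genes and 13 were lower when adjusted over the list alone. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had 22 of 22 members positive (median 3.51, unchanged with H2BC3, which had 0 counts in a group, at its bound). That list passed camera (5.22e-07, fry 0.38, adjusted p = 0.947 with an estimated correlation), 5 members were higher adjusted over the list alone, and the call was lost without shCCDC50-1 replicate 1 (0.252), the library with 13.2% rRNA. The median was 4.17 in that library and 0.41 in its partner.

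Glioma stem and proneural genes (10 of 15 lower, median −0.52, with NCAM1, a neural adhesion molecule, at −1.67) passed camera for hairpin 1 at 0.0317 but not fry (0.197). With an estimated correlation the adjusted p was 0.947, and 1 member was higher and 5 lower adjusted over the list alone. The call was lost without shCtrl replicate 1 (0.0543) or 2 (0.0617) and without hairpin 1 replicate 1 (0.146) or 2 (0.114). NRF2 targets, antioxidant genes such as AKR1C1 (−1.15), had 14 of 21 members lower (median −0.21) and 3 lower adjusted over the list alone. They passed camera at 0.0483 (fry 0.164, adjusted p = 0.947 with an estimated correlation), and not without shCtrl replicate 1 (0.0927) or 2 (0.131), hairpin 1 replicate 1 (0.346) or 2 (0.0959), or hairpin 5 replicate 1 (0.0644) or 2 (0.0646). The MAPK list had a median of 0.02 and a mean of −0.01 (13 members each way, adjusted p = 0.821), and 4 of its members were higher and 6 lower adjusted over the list alone. The NF-kB list had a median of −0.13 (0.855). In settings chosen after the data were seen, NRF2 targets did not pass with the length trend removed (0.0601), and without shCCDC50-1 replicate 1 and shCCDC50-5 replicate 2 together histones (0.162), glioma stem genes (0.0853) and NRF2 targets (0.413) did not. NRF2 targets also missed the threshold with RLE scaling (0.0513).

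For single genes, hairpin 1 against the control gave 0 calls by edgeR's quasi-likelihood test (smallest adjusted p 0.0561), with 2314 genes at an unadjusted p under 0.05, 589 calls by DESeq2 and 5 by limma-voom. The count was 30 without hairpin 1 replicate 2, 2835 without hairpin 5 replicate 1 and 2866 without hairpin 5 replicate 2, and 0 without each of the other 3 libraries. Among the genes tied at that smallest adjusted p, picked after their values were seen, were CHI3L1, a secreted glycoprotein of mesenchymal glioblastoma (2.88, SE 0.210), the early-response transcription factor EGR1 (−2.18, SE 0.183) and the collagenase MMP1 (2.11, SE 0.192).

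With hairpin 5, 3 cytokine genes of the NF-kB list fell. IL1B, a pro-inflammatory cytokine, dropped from 264 and 245 CPM in the controls to 17.2 and 16.1 (log2 −3.93, SE 0.180, adjusted p = 0.00396), and the neutrophil-recruiting chemokines CXCL2 (−1.86, SE 0.208, 0.0334) and CXCL8 (−1.62, SE 0.211, 0.0415) fell with it. In the NF-kB list 22 of 26 members were negative (median −0.61), these 3 were called, and 9 were lower adjusted over the list alone. MAPK feedback and output genes also fell, with 22 of 26 members negative (median −0.58), 13 lower adjusted over the list alone, and 3 called: EGR1 (−1.68, SE 0.179, 0.0334), the receptor kinase inhibitor SPRY2 (−1.15, SE 0.151, 0.0421) and the AP-1 subunit FOSL1 (−1.50, SE 0.187, 0.0384). Camera gave adjusted p = 6.8e-07 for the MAPK list and 1.54e-06 for the NF-kB list, fry gave 0.00194 for each, and camera gave adjusted p = 0.159 with an estimated correlation for each. In the 2 hairpin 5 libraries the medians were −0.45 and −0.69 for MAPK and −0.68 and −0.57 for NF-kB. Among EGFR ligands EREG fell (−1.40, SE 0.191, 0.0443), and the EGFR family list as a whole had 10 of 12 members negative and a median of −0.35 (adjusted p = 0.0643). Adjusted over the list alone, 2 of these were lower.

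ER stress and ATF4 genes were lower with hairpin 5 as well: 26 of 33 members were negative (median −0.36, camera 0.000106, fry 0.00232, adjusted p = 0.159 with an estimated correlation), with 0 called, 1 higher and 13 lower adjusted over the list alone. CHAC1 stood at −1.98, SLC7A11 at −1.82 and ATF3, a stress-induced transcription factor, at −1.43 (adjusted p = 0.0548). YAP/TAZ targets, which respond to cell tension, had 18 of 20 members negative (median −0.51, camera 0.000545, fry 0.132, adjusted p = 0.506 with an estimated correlation), 1 lower adjusted over the list alone. Their medians were −0.18 and −1.02 in the 2 libraries, and the call was lost without hairpin 5 replicate 2 (0.0597). In the list of matrix proteases and inhibitors 14 of 19 members were negative (median −0.25), MMP1 fell (−1.63, SE 0.189, 0.0347) and the lysosomal collagenase CTSK rose (1.73, SE 0.196, 0.0334), with 1 higher and 5 lower adjusted over the list alone. That list passed at 0.0288 (fry 0.049, adjusted p = 0.329 with an estimated correlation), and not without shCtrl replicate 1 (0.0753), hairpin 5 replicate 1 (0.0513) or hairpin 5 replicate 2 (0.0597).

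Ribosomal protein and nuclear OXPHOS genes passed camera as higher with hairpin 5, through replicate 2, the library where level fell with length. Ribosomal protein genes had 50 of 52 members positive (median 0.37, camera 0.015, fry 0.582, adjusted p = 0.791 with an estimated correlation), with medians of −0.14 in replicate 1 and 0.73 in replicate 2. The call was lost without shCtrl replicate 2 (0.0761), and without hairpin 5 replicate 2 the list passed in the other direction (0.00336). Nuclear OXPHOS genes, which encode respiratory chain subunits such as COX7C (1.30), had 28 of 34 positive (median 0.29, camera 0.0192, fry 0.48, adjusted p = 0.768 with an estimated correlation), with medians of −0.03 and 0.54. They did not pass without shCtrl replicate 1 (0.0855) or 2 (0.0512), and the direction reversed without hairpin 5 replicate 2 (0.714). No member of either list was called, also when adjusted over the list alone. Histones had 22 of 22 members positive (median 2.01, camera 8.02e-05, fry 0.256, adjusted p = 0.556 with an estimated correlation), 3 higher adjusted over the list alone, in libraries with 2.62% and 2.72% rRNA.

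A further 5 lists stood higher with hairpin 5 by camera and were lost with an estimated correlation. Epithelial markers (median 0.85, 10 of 11 positive, 4 higher adjusted over the list alone) passed at 0.007 (fry 0.0538, adjusted p = 0.329 with an estimated correlation), and not without hairpin 5 replicate 2 (0.137). Hypoxia and glycolysis genes (median 0.24, 25 of 32 positive, 0 adjusted over the list alone) passed at 0.0192 (fry 0.0658, adjusted p = 0.512 with an estimated correlation). That call was lost without shCtrl replicate 1 (0.051) or 2 (0.127), hairpin 1 replicate 1 (0.0668) or 2 (0.0679), or hairpin 5 replicate 1 (0.0919). Class I antigen presentation (median 0.41, 11 of 15 positive, 4 adjusted over the list alone, with HLA-B at 0.88) passed at 0.0322 (fry 0.0456, adjusted p = 0.329 with an estimated correlation). It did not pass without shCtrl replicate 1 (0.0885) or 2 (0.0815), hairpin 1 replicate 1 (0.0668) or 2 (0.0792), or hairpin 5 replicate 1 (0.0513). Neuron markers (median 0.36, 7 of 10 positive, 3 adjusted over the list alone), among which the growth-cone protein gene GAP43 rose (1.18, SE 0.164, 0.0463), passed at 0.0322 (fry 0.00194, adjusted p = 0.329 with an estimated correlation). This was lost without shCtrl replicate 2 (0.139), hairpin 1 replicate 1 (0.0978) or 2 (0.096), or hairpin 5 replicate 1 (0.168) or 2 (0.0617). Interferon response genes (median 0.36, 26 of 37 positive, 3 adjusted over the list alone, with BST2, an antiviral tether, at 2.62) passed at 0.0341 (fry 0.0847, adjusted p = 0.329 with an estimated correlation). They did not pass without shCtrl replicate 2 (0.171), hairpin 1 replicate 1 (0.0668) or 2 (0.0679), or hairpin 5 replicate 1 (0.0919) or 2 (0.112). Astrocyte markers passed fry as higher (0.0375) but not camera (0.0643).

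More list calls for hairpin 5 ended in other settings, of which the first 2 were chosen after the data were seen. With the length trend removed, ribosomal protein genes (0.453), OXPHOS genes (0.488) and matrix proteases (0.226) did not pass camera. Calls lost without shCCDC50-1 replicate 1 and shCCDC50-5 replicate 2 together were interferon response (0.136), class I antigen presentation (0.0628), matrix proteases (0.0883), YAP/TAZ targets (0.0685), neuron markers (0.128) and epithelial markers (0.136). Matrix proteases were also lost with the filter of 1 CPM in 2 libraries (0.0666).

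In all, edgeR called 102 genes for hairpin 5 against the control, 66 higher and 36 lower, 93 of them protein-coding, with 3128 genes at an unadjusted p under 0.05. The largest rises by the naming rule were in genes low in the controls. LBP, the lipopolysaccharide-binding protein gene, had 0 counts with shCtrl and 808 with hairpin 5 (at least 350-fold higher, adjusted p = 0.0334). DUSP27, a pseudophosphatase gene (log2 7.69, SE 0.818), the zinc-finger gene ZNF423 (6.47, SE 0.568), the nitric oxide synthase gene NOS1 (6.38, SE 0.855, with 191 and 35.7 CPM in the 2 libraries), the sulfotransferase gene SULT1A1 (4.72, SE 0.443), which has close paralogs that may share reads, and the liver transcription factor gene CREB3L3 (4.22, SE 0.351) also rose. Besides IL1B, the protease inhibitors TFPI2 (−2.43, SE 0.286) and SERPINB2 (−2.07, SE 0.217), the potassium channel gene KCNN3 (−2.26, SE 0.282) and the transporter gene SLC16A6 (−2.05, SE 0.246) fell. The readthrough gene HNRNPUL2-BSCL2 had 0 counts in both hairpin 5 libraries (at least 2120-fold lower), but it overlaps HNRNPUL2 and BSCL2, and the 3 rows summed to 804 and 825 CPM in the controls and 880 and 623 with hairpin 5. No call remained without either shCtrl library, 8 genes passed without hairpin 1 replicate 1 (6 of the 102), 5 without hairpin 1 replicate 2 (4 of the 102), 6793 without hairpin 5 replicate 1 (all but 1 of the 102) and 1947 without hairpin 5 replicate 2 (100 of the 102).

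The difference between the hairpins was tested directly. MMP1 was lower with hairpin 5 than with hairpin 1 (log2 −3.74, SE 0.205, adjusted p = 0.00651), at 79.5 and 81.1 CPM in the controls, 330 and 363 with hairpin 1 and 29.1 and 22.8 with hairpin 5. IL1B (−4.09, SE 0.181, 0.00322) and the monocarboxylate transporter gene SLC16A6 (−3.90, SE 0.261, 0.0118) were also lower, as were the cytokine gene TNFSF14 (−3.12), TFPI2 (−2.69), SERPINB2 (−2.58), CXCL2 (−1.65) and CHI3L1 (−1.45). Higher with hairpin 5 were DUSP27 (7.46), the calcitonin-related gene CALCB (7.08), LBP (6.74, from 7 counts with hairpin 1), NOS1 (5.82), ZNF423 (5.62), the adhesion receptor gene ADGRA2 (4.69), CREB3L3 (4.19), the muscle filament gene DES (3.85), the tight-junction gene CLDN7 (3.19), the synaptic vesicle gene SYP (1.84), the protease inhibitor gene TIMP3 (1.37), the mitochondrial reductase gene FDXR (1.32) and the proteoglycan gene CSPG4 (1.18). HNRNPUL2-BSCL2 was at least 1570-fold lower. By edgeR 160 genes passed, 102 higher and 58 lower, with 3163 at an unadjusted p under 0.05. The count was 4 without shCtrl replicate 1, 4 without shCtrl replicate 2, 3 without hairpin 1 replicate 1, 0 without hairpin 1 replicate 2 (DESeq2 called 958 and limma-voom 105 with all libraries), 6507 without hairpin 5 replicate 1 and 2331 without hairpin 5 replicate 2.

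Of the fixed lists, NF-kB targets (median −0.72, 21 of 26 lower, camera 2.14e-05, fry 0.00259) and MAPK output (median −0.49, 22 of 26 lower, camera 3.97e-05, fry 0.00424) were lower with hairpin 5 than with hairpin 1, each with adjusted p = 0.277 with an estimated correlation. Adjusted over the list alone, 1 NF-kB gene was higher and 10 lower, and 1 MAPK gene was higher and 8 lower. Called members outside the naming rule, chosen after their values were seen, were LIF, an IL-6 family cytokine (−2.41, SE 0.264), the ERK phosphatase DUSP6 (−1.37, SE 0.165) and the chromatin protein HMGA2 (−1.44, SE 0.160). YAP/TAZ targets (median −0.53, 16 of 20 lower, 2 lower adjusted over the list alone, with CCN2 at −1.17) passed at 0.0183 (fry 0.215, adjusted p = 0.619 with an estimated correlation), and not without hairpin 1 replicate 1 (0.0803) or hairpin 5 replicate 2 (0.316). Ribosomal protein genes (median 0.40, 52 of 52 higher, 0 adjusted over the list alone) passed at 0.0102 (fry 0.636, adjusted p = 0.897 with an estimated correlation). They did not pass without hairpin 1 replicate 1 (0.0868), and their direction reversed without hairpin 5 replicate 2 (0.0682), the library with the length trend.

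The other 5 lists with a difference between the hairpins were each lost with an estimated correlation and when libraries were left out. Matrix proteases and inhibitors (median −0.30, 13 of 19 lower, TIMP3 called higher and MMP1, TIMP2 and PLAU called lower, 2 higher and 5 lower adjusted over the list alone) passed at 0.041 (fry 0.0229, adjusted p = 0.602 with an estimated correlation). Without shCtrl replicates 1 and 2, hairpin 1 replicates 1 and 2 and hairpin 5 replicates 1 and 2 in turn the value was 0.0556, 0.0557, 0.0516, 0.0731, 0.0596 and 0.118. Class I antigen presentation (median 0.36, 11 of 15 higher, 4 higher adjusted over the list alone) passed at 0.0431 (fry 0.0235, adjusted p = 0.602 with an estimated correlation), and in the same order the values were 0.0855, 0.0865, 0.0868, 0.116, 0.069 and 0.0733. Hypoxia and glycolysis (median 0.17, 27 of 32 higher, 2 higher adjusted over the list alone) also stood at 0.0431 (fry 0.0642, adjusted p = 0.602 with an estimated correlation). Its called members, the carbonic anhydrase CA9 (2.25, SE 0.341) and NDRG1 (1.49, SE 0.165), were named after their values were seen. The list did not pass without shCtrl replicate 1 (0.0919) or 2 (0.0945), hairpin 1 replicate 1 (0.0521) or 2 (0.296), or hairpin 5 replicate 1 (0.321). G1/S and DNA replication genes (median −0.21, 21 of 33 lower, 1 lower adjusted over the list alone, with the cyclin gene CCNE1 at −1.04) passed at 0.0431 (fry 0.208, adjusted p = 0.709 with an estimated correlation), and not without shCtrl replicate 1 (0.0818) or 2 (0.0837), hairpin 1 replicate 2 (0.296) or hairpin 5 replicate 1 (0.542). Mitochondrially encoded genes (median 0.42, 11 of 13 higher, 0 adjusted over the list alone) passed at 0.0439 (fry 0.307, adjusted p = 0.709 with an estimated correlation), and not without shCtrl replicate 1 (0.0855) or 2 (0.0865), hairpin 1 replicate 2 (0.493) or hairpin 5 replicate 2 (0.244). By fry alone, ER stress and ATF4 genes (0.0229, camera 0.328), NRF2 targets (0.031, camera 0.071), neuron markers (0.0229, camera 0.242) and p53 targets (0.0282, camera 0.1) passed as higher with hairpin 5.

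For hairpin 5 against hairpin 1, removing the length trend, a setting chosen after the data were seen, ended the calls of ribosomal protein genes (0.0716), hypoxia genes (0.0531), matrix proteases (0.084) and mitochondrially encoded genes (0.084). Also chosen then, the fit without shCCDC50-1 replicate 1 and shCCDC50-5 replicate 2 together ended those of YAP/TAZ targets (0.664), matrix proteases (0.106) and class I antigen presentation (0.111).

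**Figure D3:**
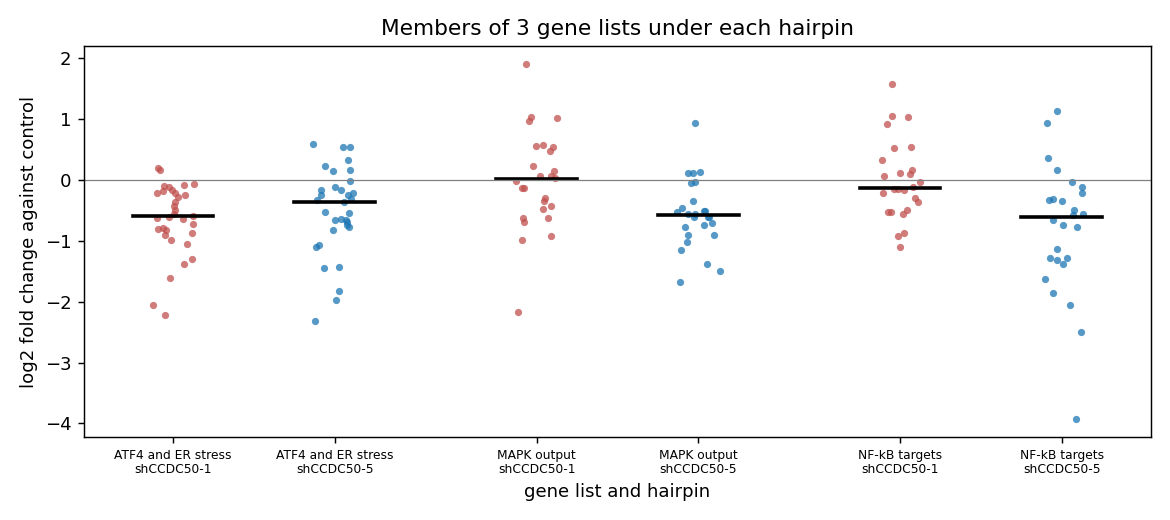
Log2 fold changes against shCtrl of the members (points) of the ER stress and ATF4, MAPK and NF-kB lists for each hairpin, with the median of each as a line. The medians for hairpins 1 and 5 are −0.58 and −0.36, 0.02 and −0.58, and −0.13 and −0.61.

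What the hairpins shared was asked with the mean of the hairpins against the control. EGR1, an immediate early transcription factor (log2 −1.93, SE 0.146, adjusted p = 0.0341), and IL1B (−1.89, SE 0.133, 0.0341) fell, and CHI3L1 rose (2.16, SE 0.189, 0.0375). For IL1B the mean rests on hairpin 5, since hairpin 1 alone stood at 0.16, while EGR1 and CHI3L1 had the same sign with each hairpin. Also called, and named after their values were seen because only 7 genes passed, were the membrane glycoprotein gene GPNMB (2.35, SE 0.196, 0.0375), the bone-related genes TMEM119 (2.46, SE 0.186, 0.0341) and SOST (3.12, SE 0.272, 0.0375), and the serine incorporator gene SERINC2 (3.88, SE 0.334, 0.0375). These 5 higher and 2 lower genes passed edgeR's test, with 2589 at an unadjusted p under 0.05. Without each of the shCtrl and hairpin 1 libraries 0 passed (DESeq2 called 684 and limma-voom 9 with all libraries), against 5503 without hairpin 5 replicate 1 and 2376 without hairpin 5 replicate 2.

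No gene was called by both hairpins by edgeR, since hairpin 1 gave 0 calls. By DESeq2 114 genes were called higher and 52 lower by both hairpins and 18 in opposite directions, against 9.78 and 6.25 for independent lists, and limma-voom called 2 with the same sign. Independent lists leave out the shared controls, from which part of that excess may come, and no simulation was run for DESeq2 calls. At an unadjusted p under 0.05, 455 genes were higher and 357 lower with both hairpins and 94 opposite. Simulated unchanged groups with 1 shared control gave 129 higher, 77.8 lower and 3.68 opposite. The simulation used the same spread per gene in all libraries. The real control libraries differed less, with an SD of the log2 difference of 0.691 against 0.995 for hairpin 1 and 1.05 for hairpin 5. The simulation may thus overstate what shared controls add, and it does not settle how much of the observed agreement they explain. Without hairpin 1 replicate 2 the number called by both was 1, and it was 1388 without hairpin 5 replicate 1 and 668 without hairpin 5 replicate 2. Across genes the log2 changes correlated at r = 0.410, below the mean of 0.481 (lowest to highest of 40 simulations 0.447 to 0.511) of simulated unchanged groups with shared controls. Their covariance of 0.549 was above the simulated mean of 0.301 (lowest to highest 0.268 to 0.331). The sign was the same for 63.4% of genes, against 66.3% in the simulation.

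**Figure D4:**
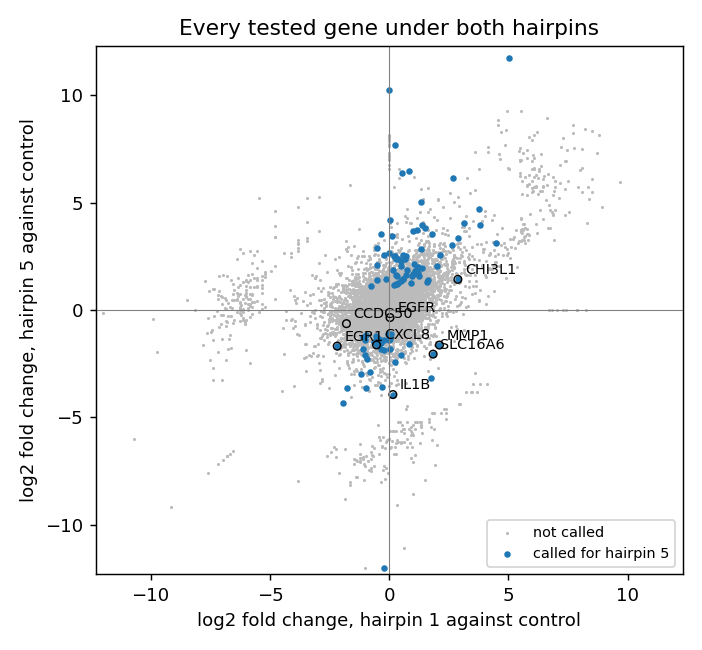
Log2 fold change against shCtrl for hairpin 1 (horizontal axis) and hairpin 5 (vertical axis), 1 point per tested gene, with axes limited at 12 and 3 values drawn at that limit. The correlation across genes is 0.410.

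ER stress and ATF4 genes were the list with the smallest adjusted p for the mean of the hairpins: 28 of 33 members were lower (median −0.44, camera 1.38e-07, fry 0.00235, adjusted p = 0.207 with an estimated correlation), 0 were called and 15 were lower adjusted over the list alone. Its 4 named members were CHAC1 (−2.10, SE 0.256), SLC7A11 (−1.94, SE 0.239), ASNS (−1.22, SE 0.155) and ATF3 (−1.15, SE 0.176), and the list passed without each library. NF-kB targets (19 of 26 lower, median −0.37, 5 lower adjusted over the list alone) passed at 0.00121 (fry 0.00534) and MAPK output (20 of 26 lower, median −0.23, 6 lower adjusted over the list alone) at 0.00181 (fry 0.00604), each with adjusted p = 0.354 with an estimated correlation. In both lists the shift lay with hairpin 5. YAP/TAZ targets (18 of 20 lower, median −0.35, 0 adjusted over the list alone) passed at 0.0144 (fry 0.304, adjusted p = 0.641 with an estimated correlation), and not without shCtrl replicate 1 (0.0574), hairpin 1 replicate 2 (0.0786) or hairpin 5 replicate 2 (0.0615). Glioma stem and proneural genes (12 of 15 lower, median −0.28, with NCAM1 at −1.48, 1 higher and 6 lower adjusted over the list alone) passed at 0.02 (fry 0.141, adjusted p = 0.618 with an estimated correlation), and not without shCtrl replicate 2 (0.0593) or hairpin 1 replicate 1 (0.0539) or 2 (0.0758).

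Higher for the mean of the hairpins were histones (22 of 22, median 2.76, 3 higher adjusted over the list alone, 2.77e-07, fry 0.229, adjusted p = 0.618 with an estimated correlation), in the libraries that held more rRNA. Interferon response genes (27 of 37 higher, median 0.26, 0 adjusted over the list alone, with TRIM22 at 0.69) passed at 0.02 (fry 0.127, adjusted p = 0.465 with an estimated correlation), and not without shCtrl replicate 2 (0.181) or hairpin 1 replicate 2 (0.0758). Epithelial markers (10 of 11 higher, median 0.42, 0 adjusted over the list alone, with the keratin gene KRT7 at 0.72) passed at 0.0144 (fry 0.141, adjusted p = 0.465 with an estimated correlation), and not without shCtrl replicate 1 (0.0853) or 2 (0.0527), hairpin 1 replicate 1 (0.0539) or hairpin 5 replicate 2 (0.147). Nuclear OXPHOS genes (26 of 34 higher, median 0.20, 0 adjusted over the list alone) passed at 0.0395 (fry 0.733, adjusted p = 0.879 with an estimated correlation), and not without shCtrl replicate 1 (0.219) or 2 (0.0899), hairpin 1 replicate 1 (0.0539) or 2 (0.142), or hairpin 5 replicate 2 (0.681), the library with the length trend. In settings chosen after the data were seen, the calls for the mean that ended with the length trend removed were YAP/TAZ targets (0.0504), glioma stem genes (0.054) and OXPHOS genes (0.537). Those that ended without shCCDC50-1 replicate 1 and shCCDC50-5 replicate 2 together were MAPK output (0.059), interferon response (0.0644), glioma stem genes (0.0652), epithelial markers (0.345) and OXPHOS genes (0.449).

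The lists closest to the question of the series did not pass camera for the mean of the hairpins. EGFR family and ligands had 9 of 12 members negative (median −0.18, adjusted p = 0.207), with EREG at −0.98 and 2 lower adjusted over the list alone. Endosomal sorting and recycling genes had 20 of 35 negative (median −0.11, 0.206), with the ESCRT-0 gene STAM at −0.59, the ubiquitin ligase gene CBL at −0.68 and the recycling effector gene RAB11FIP2 at −0.65. Autophagy and lysosome genes had 19 of 33 positive (median 0.06, 0.674), with the cathepsin gene CTSD at 1.01. No member of the latter 2 lists passed adjusted over the list alone. The 3 lists had medians of −0.12, −0.04 and 0.03 with hairpin 1 and of −0.35, −0.06 and 0.06 with hairpin 5, where the endosomal median turned positive under upper-quartile scaling.

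The lists of this paragraph did not pass camera or fry for the mean of the hairpins. G1/S genes had a median of −0.01 and a mean of 0.00 (0.916), and the median turned positive under upper-quartile scaling. G2/M genes had 26 of 37 negative (median −0.10, 0.178), and passed without hairpin 5 replicate 2 (0.0223). For both, 0 members passed adjusted over the list alone. p53 targets had a median of 0.08 and a mean of −0.03 (0.988), with the growth-arrest gene CDKN1A at −0.77 and 3 lower adjusted over the list alone. Apoptosis regulators had a median of 0.09 (0.916, tested as higher) and NRF2 targets a median of −0.02 (0.463), which turned positive under upper-quartile scaling. Adjusted over the list alone, 0 apoptosis genes passed and 1 NRF2 gene was higher and 4 lower. Hypoxia and glycolysis genes had a median of 0.10 (0.206, and 0.0462 without hairpin 5 replicate 2), with 5 higher and 2 lower adjusted over the list alone, cholesterol biosynthesis genes a median of 0.09 (0.78), and fatty acid synthesis genes a median of −0.11 with a mean of 0.01 and a test in the higher direction (0.936). In the lipid lists 0 passed adjusted over the list alone.

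None of the remaining lists passed camera for the mean of the hairpins with all libraries, TMM and filterByExpr at the preset correlation, and of these only neuron markers passed fry. Extracellular matrix genes had a median of −0.17 and a mean of 0.15 (0.697), with the microfibril gene FBN2 at −1.80 and the crosslinking enzyme gene LOX at −1.06, and 2 higher and 4 lower adjusted over the list alone. Its member BGN had 0 counts in a group, and at its bound the medians for each hairpin and for hairpin 5 against hairpin 1 did not move. The mean of the hairpins was not run with that bound. Matrix proteases had a median of −0.10 (0.537, 1 higher adjusted over the list alone). TGF-beta targets had 14 of 19 negative (median −0.29, 0.0674, but 0.0282 without hairpin 5 replicate 2 and 0.0354 by camera with a mean-variance trend), with 2 higher and 3 lower adjusted over the list alone, and PMEPA1, an inhibitor of the pathway, fell with hairpin 5 (−1.43, SE 0.171, 0.0347). The mesenchymal list had a median of 0.08 with a test in the lower direction (0.762), 1 higher and 4 lower adjusted over the list alone, its member CHI3L1 was called as given above, and its member NAMPT, which makes NAD, fell with hairpin 5 (−1.34, SE 0.160, 0.0347). Astrocyte markers had a median of 0.40 (0.0939, and 0.0477 without hairpin 5 replicate 2) and neuron markers a median of 0.32 (0.0867, fry 0.0178, 0.0474 with the mean-variance trend and 0.0424 with the filter of 1 CPM), with 0 and 2 higher adjusted over the list alone. Immune markers had a median of −0.15, a mean of 0.07 and a test in the higher direction (0.678), with 1 higher adjusted over the list alone. Endothelial and pericyte markers had a median of −0.04, which turned positive under upper-quartile scaling, a mean of 0.01 and a test in the higher direction (0.916), with 2 higher and 2 lower adjusted over the list alone, and DES rose with hairpin 5 (3.52, SE 0.443, 0.0385). Class I antigen presentation had a median of 0.12 (0.323) and mitochondrially encoded genes a median of 0.12 (0.744). Ribosomal protein genes had a median of 0.14 (0.206), passed without hairpin 5 replicate 1 (4.63e-09) and passed in the lower direction without hairpin 5 replicate 2 (0.0223). In these last 3 lists 0 passed adjusted over the list alone.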

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

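The 8 tests of explanations below were chosen only after the result they examine was seen, while the comparison of the hairpins with each other was planned.

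Counts on rRNA rows, which are part of the library totals but were not compared between groups as a class, stood above the highest control share (0.235%) in 3 knockdown libraries: 13.2% in hairpin 1 replicate 1, and 2.62% and 2.72% in the hairpin 5 libraries.

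The hairpins target the same gene, and the test of hairpin 5 against hairpin 1 found differences between them. For lists, the median log2 difference was −0.49 for MAPK output, −0.72 for NF-kB targets, 0.36 for class I antigen presentation, −0.21 for G1/S genes, 0.17 for hypoxia genes, −0.30 for matrix proteases, −0.53 for YAP/TAZ targets, 0.40 for ribosomal proteins and 0.42 for mitochondrially encoded genes, by camera with its preset correlation and in none of these 9 with an estimated one. For secreted proteins, enzymes and cytokines, the log2 difference was −4.09 for IL1B, −3.74 for MMP1, −3.12 for TNFSF14, −2.69 for TFPI2, −2.58 for SERPINB2, −1.65 for CXCL2, −1.45 for CHI3L1, 1.37 for TIMP3, 6.74 for LBP, 7.08 for CALCB, 7.46 for DUSP27, 5.82 for NOS1 and 1.32 for FDXR. For transporters, transcription factors, surface and structural proteins it was −3.90 for SLC16A6, 5.62 for ZNF423, 4.19 for CREB3L3, 4.69 for ADGRA2, 3.85 for DES, 3.19 for CLDN7, 1.84 for SYP and 1.18 for CSPG4. All 21 genes passed edgeR's test.

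Replication-dependent histones, whose mRNAs end without a poly(A) tail, had medians of 4.17, 0.41, 2 and 1.63 in the 4 knockdown libraries against the controls. More cells in S phase would raise the G1/S genes too, but in the 3 libraries with a histone median over 1 the upper quartile of the G1/S members was at most 0.35. Carry-over of RNA without a poly(A) tail may be the cause: 61 other such RNAs differed by a median of 4.97 (interquartile range 1.23 to 7.23) between the hairpin 1 libraries, and their medians of 4.91, −0.17, 2.13 and 1.25 rank the libraries in the same order as the histones. An effect of the knockdown cannot be told apart from this, because the hairpin 1 libraries differ from each other by 3.76 while the hairpin 5 libraries, which differ by 0.37, both held more rRNA than the controls. How RNA was selected is not given in the sources used here.

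Ribosomal protein and OXPHOS genes stood higher with hairpin 5, at medians of 0.73 and 0.54 in replicate 2 but −0.14 and −0.03 in replicate 1. A knockdown effect on ribosomal protein genes in all 4 libraries is argued against, since the highest median in the other 3 libraries was −0.03, with upper quartiles of −0.02, 0.12 and 0.01. The length trend of hairpin 5 replicate 2 could account for part: 901 other genes of lengths like those of the ribosomal list stood higher by a median of 0.30 there, and 641 matched to OXPHOS genes by 0.28. With the trend removed, the fold of the ribosomal list went from 0.37 (SD over members 0.19) to 0.10 (0.26) and that of OXPHOS from 0.29 (0.37) to 0.08 (0.45), so the camera calls ended because the medians dropped (adjusted p = 0.453 and 0.488), and without that correction both were lost by fry (0.582 and 0.48) and at adjusted p = 0.791 and 0.768 with an estimated correlation. Whether the trend is the whole cause cannot be told apart from another property of that library, since the shift lies in 1 library. The shift of matched genes was less than that of the lists, but this does not decide the question. Genes were matched on the longest annotated transcript (median 1864.5 bases for the ribosomal list), which may not be the transcript expressed.

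MAPK and NF-kB genes were lower with hairpin 5, at medians of −0.58 and −0.61. The length trend is argued against, since with it removed the medians were −0.54 (SD over members 0.59) and −0.70 (1.16) and the larger camera adjusted p was 4.16e-06 (without the correction for length, adjusted p = 0.159 with an estimated correlation for each list). The amount of CCDC50 mRNA left is also argued against: hairpin 5 left more of it than hairpin 1, by 1.16 (95% interval 0.67 to 1.64, adjusted p = 0.0718, which did not pass), yet had the lower lists, with a larger fry adjusted p of 0.00424 for the difference between hairpins (camera adjusted p = 0.277 with an estimated correlation for each). Single MAPK members fell with hairpin 1 too: EGR1 (log2 −2.18, against −1.68 with hairpin 5) and SPRY2 (−0.98, against −1.15). DESeq2 called both genes with each hairpin, edgeR only with hairpin 5, and as many MAPK members rose as fell with hairpin 1. For the lists as a whole, an effect private to hairpin 5 may be the cause. It cannot be told apart from a dependence on CCDC50 protein, which was not analysed here. This is because there are only 2 hairpins and their sequences are not given in the sources used here. Nor can another property of the hairpin 5 libraries be told apart, since hairpin and library pair coincide. They held 2.62% and 2.72% rRNA, against at most 0.235% in the controls, and lay at 36.5 and 102 on the first principal component, against −52.8 to −23.9 elsewhere. Hairpin 1 replicate 1, with 13.2% rRNA, had medians of 0.001 for MAPK and −0.007 for NF-kB.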

How the results depend on the processing

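Sample quality weights, removal of the length trend, leaving out hairpin 1 replicate 1 and hairpin 5 replicate 2 together, and camera with a mean-variance trend were chosen only after the data were seen, and the other settings were chosen before the data were examined. The cause was not tested for any change listed here unless it is stated.

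Counts of called genes are given in the order hairpin 1, hairpin 5, both hairpins, hairpin 5 against hairpin 1, and mean of the hairpins, against 0, 102, 0, 160 and 7 by edgeR with all libraries. Without a filter they were 151, 360, 53, 366 and 213. With 1 CPM in 2 libraries they were 17, 125, 8, 199 and 18, and with only symbol rows 13, 126, 6, 174 and 35, where fewer genes were tested. DESeq2 gave 589, 992, 166, 958 and 684, and limma-voom 5, 157, 2, 105 and 9. A fit of the compared groups alone, with the hairpins pooled as 1 group for the mean, gave 2933, 5, 1, 0 and 0. Replicate number as a block gave 0, 7, 0, 7 and 0, and the numbers do not pair the libraries: the deviations of libraries with the same number correlated at 0.032, −0.026 and 0.034. The block ended the list calls of NRF2 targets with hairpin 1 (0.0814) and neuron markers with hairpin 5 (0.0543), and for hairpin 5 against hairpin 1 those of class I antigen presentation (0.064), hypoxia (0.064), matrix proteases (0.0629), G1/S (0.0854) and mitochondrially encoded genes (0.0854). An adjusted p under 0.01 gave 0, 3, 0, 2 and 0. Sample quality weights gave 2086, 148, 61, 104 and 684, the length correction 135, 313, 48, 285 and 167, and leaving out the 2 libraries together 4150, 3767, 1362, 3648 and 4308.

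Leaving out 1 library gave 0 to 2866 calls for hairpin 1, 0 to 6793 for hairpin 5, 0 to 1388 for both, 0 to 6507 for hairpin 5 against hairpin 1 and 0 to 5503 for the mean. The highest counts came without a hairpin 5 library and the lowest without a control or hairpin 1 library. Each such fit assumes that the lone library of a group varies like the other groups. With the 2 libraries left out together, the spread comes from the shCtrl pair alone, which differed least (SD of the log2 difference 0.691, against 0.995 for hairpin 1 and 1.05 for hairpin 5). Every count and call of that fit rests on this pair. Of the 102 hairpin 5 calls, DESeq2 kept 102, limma-voom 91, quality weights 84, the length correction 98, the fit without the 2 libraries 102, the fit of the compared groups 4, the block 7 and an adjusted p under 0.01 3. Without either control library 0 were kept, without hairpin 1 replicates 1 and 2 6 and 4, and without hairpin 5 replicates 1 and 2 all but 1 and 100, and none changed sign in any setting. The correlation between the hairpins was 0.410 and lay between 0.285 and 0.580 when 1 library was left out, with the highest values without a control library.

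CCDC50 stayed lower under every setting and passed under some. For hairpin 1 it passed without a filter (−1.83), by DESeq2 (−1.78), in a fit of the compared groups (−1.78), with quality weights (−1.81), with the length correction (−1.72) and without the 2 libraries (−1.92), and leaving out 1 library gave −1.92 to −1.67, passing only without a hairpin 5 library. For hairpin 5 it passed without the 2 libraries (−0.45) and without hairpin 5 replicate 1, and leaving out 1 library gave −0.88 to −0.45. For the mean it passed without a filter (−1.24), by DESeq2 (−1.21), with quality weights (−1.22), with the length correction (−1.02) and without the 2 libraries (−1.18), and leaving out 1 library gave −1.33 to −1.11, passing only without a hairpin 5 library.

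Among named genes that had not passed, the sign of EGFR with hairpin 1 reversed without shCtrl replicate 2 (−0.091, with 0.168 as the highest value when 1 library was left out), as did that of NKG7, mean of hairpins against control (0.786, lowest −3.62). With the length correction the mean reversed for EGFR (0.027), RPL35 (−0.044) and MT-ATP6 (−0.16). Results of named genes that came to pass, with the same sign, numbered 50 by DESeq2, 49 with quality weights, 25 without a filter, 23 with the length correction, 99 without the 2 libraries, and 99 and 77 without hairpin 5 replicates 1 and 2. Those that no longer passed numbered 10 by limma-voom, 5 with quality weights, 4 without a filter, 24 in fits of the compared groups, 19 with the block, 24 without each shCtrl library, 21 and 24 without hairpin 1 replicates 1 and 2, and 3 and 4 without hairpin 5 replicates 1 and 2. RLE and upper-quartile scaling changed none.

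Lists called by camera numbered 4 for hairpin 1, 13 for hairpin 5, 9 for hairpin 5 against hairpin 1 and 9 for the mean. With an estimated correlation each of these was 0, with smallest adjusted p of 0.177, 0.159, 0.277 and 0.207, while fry called 1, 7, 8 and 4. Leaving out 1 library gave 1 to 3, 7 to 10, 4 to 6 and 5 to 11 lists. Without the 2 libraries 1, 8, 8 and 4 were called, and hairpin 5 against hairpin 1 gave 4 with the block and 5 with the length correction. ER stress and ATF4 genes for both hairpins and the mean, and MAPK and NF-kB genes for hairpin 5 and for hairpin 5 against hairpin 1, stayed called when each library or the 2 libraries were left out, with the block, with the length correction and by fry, but not with an estimated correlation.

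Lists reversed as follows, with adjusted p and, where 1 library was left out, the lowest and highest value. Ribosomal protein genes with hairpin 5 passed in the opposite direction without hairpin 5 replicate 2 (0.00336, range 2.06e-13 to 0.0761) and without the 2 libraries (0.00662). For hairpin 5 against hairpin 1 they reversed in the same settings (0.0682, range 3.08e-14 to 0.0868, and 0.00376, which passed), and for the mean too (0.0223, which passed, range 4.63e-09 to 0.5, and 0.148) and with the length correction (0.865). OXPHOS reversed for hairpin 5 without hairpin 5 replicate 2 (0.714, lowest 1.58e-05) and without the 2 libraries (0.962). The rest concern lists that did not pass with all libraries, and these were followed across settings only for the mean. Without shCtrl replicate 1 these were p53 targets (0.736) and cholesterol, fatty acid, endothelial and apoptosis genes (0.984 each), and without shCtrl replicate 2 fatty acid (0.986) and mitochondrially encoded genes (0.874). Without hairpin 1 replicate 1 they were G1/S (0.916), p53 (0.999) and mitochondrially encoded genes (0.916), and without hairpin 1 replicate 2 p53 (0.908), cholesterol (0.982), fatty acid (0.982) and apoptosis genes (0.908). Without hairpin 5 replicate 1 they were G1/S (0.726), fatty acid (0.726), mesenchymal (0.858) and endothelial genes (0.858). Without hairpin 5 replicate 2 they were cholesterol (0.963), autophagy (0.963), matrix (0.977) and mitochondrially encoded genes (0.818). Without the 2 libraries they were G1/S (0.95), fatty acid (0.95) and mitochondrially encoded genes (0.39), and with the length correction matrix (0.795) and mitochondrially encoded genes (0.054). G1/S genes reversed with the stricter filter (0.99), p53 (0.737) and apoptosis genes (0.852) by fry, and p53 with the mean-variance trend (0.982). The lowest values with 1 library left out were 0.228 for autophagy, 0.66 for G1/S, 0.726 for p53, 0.516 for cholesterol, 0.0641 for matrix, 0.614 for mesenchymal, 0.415 for endothelial, 0.228 for mitochondrially encoded and 0.567 for apoptosis genes, and the highest for G1/S, mesenchymal and apoptosis genes were 0.984, 0.984 and 0.986. Among list results, 35 no longer passed with an estimated correlation, 21 by fry, 17 without the 2 libraries, 11 with the length correction, 7 with the block, 1 with RLE scaling (NRF2 targets with hairpin 1), 1 with the stricter filter (matrix proteases with hairpin 5), and between 10 and 17 when 1 library was left out. For the mean, results that came to pass were neuron markers by fry (0.0178), with the stricter filter (0.0424) and with the mean-variance trend (0.0474), and TGF-beta targets with that trend (0.0354). In the other comparisons lists that had not passed were not followed here, and some passed fry, as given above. Without hairpin 5 replicates 1 and 2, 1 and 4 list results came to pass.

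In simulated data at the depth of these libraries, recovery of 2-fold changes rose from 4.76% to 55.6% for hairpin 1 when the fitted dispersion was divided by 4. Spread between libraries thus limited such calls in the simulation, but the smaller spread was not estimated from the controls. Depth was not varied in the simulation, so what it limits was not measured.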

Other observations

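The list of motile cilium genes below was written, and its tests chosen, only after 4 such genes (DNAAF1, SPEF1, RSPH4A and CFAP52) were seen among the genes DESeq2 called higher with both hairpins, and before the other members were looked at.

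A candidate hypothesis is that genes of motile cilia rise after CCDC50 knockdown. Of 91 genes listed from general knowledge, 78 were measured, and the 16 that any of the 3 gene tests called with both hairpins were set aside. The other 62 had a median log2 change of 0.48 with hairpin 1 (47 higher, 15 lower), 0.59 with hairpin 5 (51 higher, 11 lower) and 0.61 for the mean (52 higher, 10 lower), each at percentile 100 of 10000 random lists of genes with matched expression, whose central 95% ran from −0.17 to 0.15, −0.11 to 0.26 and −0.13 to 0.16. Their medians in the 4 knockdown libraries were 0.48, 0.57, 0.54 and 0.51. Camera gave unadjusted p of 9.78e-08, 1.19e-06 and 1.28e-09, and 0.00661, 0.0086 and 0.00455 with an estimated correlation. These p-values were not corrected together with the 31 fixed lists.

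Leaving out 1 library at a time, the list stayed higher, with camera p from 3.84e-07 to 2.44e-05 for hairpin 1, 1.93e-06 to 0.000875 for hairpin 5 and 1.49e-08 to 4.12e-07 for the mean. With the length trend removed its medians were 0.48, 0.65 and 0.60. Those set aside include the dynein assembly factors DNAAF1 (4.47 and 3.13 with hairpins 1 and 5, the latter passing edgeR's test at an adjusted p of 0.0463), ZMYND10 (1.45 and 1.77) and LRRC6 (1.33 and 1.30), the axonemal dynein DNAH7 (1.58 and 1.51), and the central apparatus and radial spoke genes SPEF1 (2.79 and 1.72) and RSPH4A (2.41 and 1.64). These genes were named outside the naming rule. Most were low in the controls: DNAAF1 at 0.0843 and 0.0844 CPM, RSPH4A at 0.548 and 0.478, SPEF1 at 0.955 and 0.872. ZMYND10 stood at 0.927 and 1.7, DNAH7 at 1.28 and 1.38 and LRRC6 at 10.5 and 9.21. DNAAF1 reached at most 2 CPM in a knockdown library. Among members kept in the list, control levels ran from 0 and 0.0562 CPM for SPAG17 to 150 and 158 for CFAP298. The regulators RFX2 (−0.45 and −0.28) and RFX3 (−0.27 and 0.05) did not pass, and FOXJ1 was not among the measured genes. Epithelial markers, some of which ciliated epithelium shares, also stood higher for the mean (10 of 11 members, median 0.42, camera adjusted p = 0.0144, adjusted p = 0.465 with an estimated correlation), but did not pass with hairpin 1 alone (7 of 11 higher, adjusted p = 0.619), so a wider epithelial change stays open too. All comparisons share the same 2 control libraries, so a deviation of the controls stays open beside an effect of the knockdown, and cilia were not analysed here.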
